A study of Mus musculus with 4 samples.

How the data were processed

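Hearts of 4 mice, 2 WT and 2 PRMT1-cKO, were profiled by sequencing of total RNA. Per the labels' protocols, ribosomal RNA was removed from cardiac total RNA with the RiboMinus Eukaryote kit, and libraries were made with the SOLiD total RNA-Seq kit. The submitters' processing notes name the GRCm38 build, and the aligner and the counting program are not given in the sources used here. The deposited table has 43346 genes with values for each of the 4 libraries, per the file headers. Each library's columns carry its group and replicate number, which match the sample titles, and 1 heart is 1 replicate.

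The main values are the deposited counts of gene reads, which the authors called expression values. For all 43346 genes they equal exon reads plus intron reads. The deposited counts of exon reads are almost only reads that cross an exon junction: of 2605955 exon reads in the 4 libraries 29 did not. All 2588 genes with a single exon had 0 exon reads, and 4 of them had any gene read. Reads that lie inside 1 exon are therefore nearly absent from both columns, and a gene read is a junction read or a read outside the annotated exons. Where a gene has few exon reads, its change in gene reads rests on reads outside annotated exons and need not follow its spliced RNA. For 13626 genes the table lists no exon, and all of their reads count as intron reads. It is not stated whether strand was used in counting, so reads of overlapping genes cannot be told apart; 65 of the 160 genes chosen by the rule below overlap another gene annotated in GENCODE M21. The deposited RPKM values equal exon reads scaled by exon length and by total gene reads when recomputed, and the deposited normalized signal values have identical sorted values in the 4 libraries, as quantile normalization by the authors gives. Neither was used in a test. The authors' deposited table also holds the p-value, the corrected p-value and a signed fold change score from their EDGE test with tagwise dispersions, per the file headers. By the authors' deposited table, the genes with a corrected p-value under 0.05 numbered 2725, 1354 higher and 1371 lower in PRMT1-cKO. Of the genes tested here, the authors' deposited table called 2646, and 2630 of these also changed here, all in the same direction; 524 genes changed here only. Start coordinates in the table are counted from 0: of 42462 genes matched by identifier to GENCODE M21, 33497 had an equal end and a start 1 below. Starts are printed 1-based here.

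Library sizes were 25509854 and 21701967 gene reads in WT and 18291730 and 18674587 in PRMT1-cKO, with 624897, 544891, 764806 and 671361 exon reads. Genes without an annotated exon took between 61.7 and 73.4% of the gene reads of a library. A count of 0 allows up to 3 reads, which is between 3.92 and 5.51 CPM of exon reads in these libraries; such floors cover counting error only. Whether PCR duplicates were removed is not given in the sources used here.

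Gene reads were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, glmQLFit and glmQLFTest, genotype as the only term, two-sided, Benjamini-Hochberg adjusted p under 0.05). Exon reads and intron reads were tested in the same way. Standard errors are the log2 change divided by the square root of the F statistic. Exon against intron reads within a gene were compared with diffSpliceDGE and Simes p-values over genes with both features past the filter. The median over genes of exon minus intron log2 change was 0.18. Gene lists, 38 in number, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparisons of exon reads, intron reads and their alternatives were added after the columns had been seen. The fixed design had foreseen transcript, exon or splice-event values for the splicing part; the table used here has exon and intron reads per gene, so these served as the features of each gene.

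Named genes followed a fixed rule: the PRMT family; the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 5 CPM and both PRMT1-cKO values beyond both WT values, without gene models that have only a number or clone name and without small and ribosomal RNA genes; up to 4 members per list, by size of change among those past the threshold; and for exon against intron reads the 6 genes with the smallest p and the splice list members that passed. A few genes outside the rule are named as members of small counts and were chosen after their values were seen: Mybpc2, Mybpc3, Atp1b1, Fcgr3 and C1qb. The rule was applied to gene reads and to exon reads. Clone names with the prefix RP and names with the prefix BC, which the rule did not list, were left out as well, and this was decided after the data were seen.

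Alternatives were a replicate number block, leaving out each library, RLE size factors in edgeR and the DESeq2 1.42.0 Wald test. Others were no read filter and a filter of at least 50 reads in 2 libraries. Exon reads, intron reads, and a fit without mitochondrial genes and genes with no annotated exon were added later. Alternatives planned for normalized values (pseudocounts, median and quantile scaling) were not needed because the table holds counts. The analysis was tested on simulated counts with 200 changed genes: for gene reads 44.0% of 2-fold and 89.0% of 4-fold changes were recovered among 13647 and 13488 genes, and 0% of 1.5-fold changes among 13534 genes. For exon reads 47.0% and 92.5% of 2-fold and 4-fold changes were recovered among 4499 and 4494 genes, and for exon against intron reads 12.0% and 62.5% among 4064 and 4051 genes. Of the genes called in these tests, 5.38% and 7.29% were false for gene reads at 2-fold and 4-fold, 4.08% and 2.63% for exon reads, and 7.69% and 6.72% for exon against intron reads, so the share exceeded 5% in gene reads and in the balance. For exon against intron reads the simulated dispersion was set by hand and not estimated, and exon and intron counts were drawn independently. The recovered and false shares of that comparison may therefore differ in the real data. In a simulated list test the 1 changed list was called and 0 others. There the genes were drawn independently and no gene outside that list was changed. Genes in the real data are not independent, so this cannot show how often camera calls lists falsely there. With 2 hearts per group small changes are mostly missed.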

Results

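Whole-heart RNA was profiled in mice of the C57BL/6 strain at 6 weeks of age. The series compared 2 wild-type (WT) hearts with 2 hearts from mice lacking PRMT1 in cardiomyocytes (PRMT1-cKO). PRMT1 is the main enzyme that places asymmetric dimethyl marks on arginine residues of proteins, RNA-binding proteins among them. The stated aim was to examine the mRNA profile and alternative splicing in these hearts. Reads assigned to genes numbered 25509854 and 21701967 in WT replicates 1 and 2, and 18291730 and 18674587 in PRMT1-cKO replicates 1 and 2. The mitochondrial 16S ribosomal RNA gene mt-Rnr2 alone took 65.3 ± 0.609% (SD, n = 2) of these reads in WT and 52.0 ± 1.15% (SD, n = 2) in PRMT1-cKO. Exon reads made up 2.48 ± 0.0432% (SD, n = 2) of gene reads in WT and 3.89 ± 0.414% (SD, n = 2) in PRMT1-cKO. Genes without an annotated exon, mt-Rnr2 among them, took 72.7 ± 1.04% of gene reads in WT and 62.7 ± 1.45% in PRMT1-cKO (SD, n = 2 each). They can have no exon reads, so part of the difference in exon share comes from this total.

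Prmt1 itself (ENSMUSG00000052429, chromosome 7, 44975989 to 44986492 on GRCm38) was covered by 33 and 18 gene reads in WT and 33 and 44 in PRMT1-cKO. All of these were counted as intron reads, and 0 exon reads were counted in each of the 4 libraries. The Prmt1 log2 change was 0.44 ± 0.34 (SE, n = 2 per group) with an edgeR adjusted p of 0.394. The table therefore does not show whether the deleted gene lost its exons, and heart cells other than cardiomyocytes keep the gene in this model. Among the other family members, Prmt3, which modifies a ribosomal protein, rose by a log2 change of 0.57 ± 0.20 (edgeR adjusted p = 0.0447), a call that was lost without WT replicate 1 (adjusted p = 0.156), WT replicate 2 (0.426) or PRMT1-cKO replicate 2 (0.124), and also with a replicate block, with DESeq2, without a read filter and in exon reads. Carm1 had a log2 change of 0.05 ± 0.21 and Prmt5 of 0.10 ± 0.28, and neither passed the test. Exon reads of Prmt7 fell by 1.29 on the log2 scale (edgeR adjusted p = 0.00238), while its gene reads had a log2 change of -0.44 ± 0.26 that did not pass. Prmt2, Prmt8 and Prmt10 did not pass in gene reads, and Prmt6 had too few reads to test. Of the 8 members measured, 1 rose over all genes tested and 0 when adjusted over the list alone.

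In PRMT1-cKO hearts many genes of cardiac stress and of the extracellular matrix had more RNA. Less RNA was seen for many genes of mitochondrial energy metabolism, ion channels and calcium cycling. These lists passed camera with its preset correlation and not with an estimated correlation. Nppa and Nppb, which encode natriuretic peptides of stressed heart muscle, were 16.8-fold and 18.2-fold higher in gene reads, and the collagen gene Col1a1 was 6.07-fold higher. The size for Col1a1 depends on single hearts, with 21.3 ± 10.7 CPM in WT and 129 ± 66.4 CPM in PRMT1-cKO (SD, n = 2 each). Cox7a1, a muscle subunit of cytochrome c oxidase, was 25.1-fold lower, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, was 4.15-fold lower. Of 13869 genes tested, 3154 changed in gene reads between PRMT1-cKO and WT, 1601 higher and 1553 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). More than 2-fold changes numbered 1073 higher and 972 lower. Without WT replicate 1 the count was 1869, 890 higher and 979 lower. Of the 33 gene lists tested, 19 changed against the other genes with camera at its preset correlation, and with camera at an estimated correlation 0 passed (3 had an unadjusted p under 0.05, and 6 passed with fry).

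**Figure D1:**
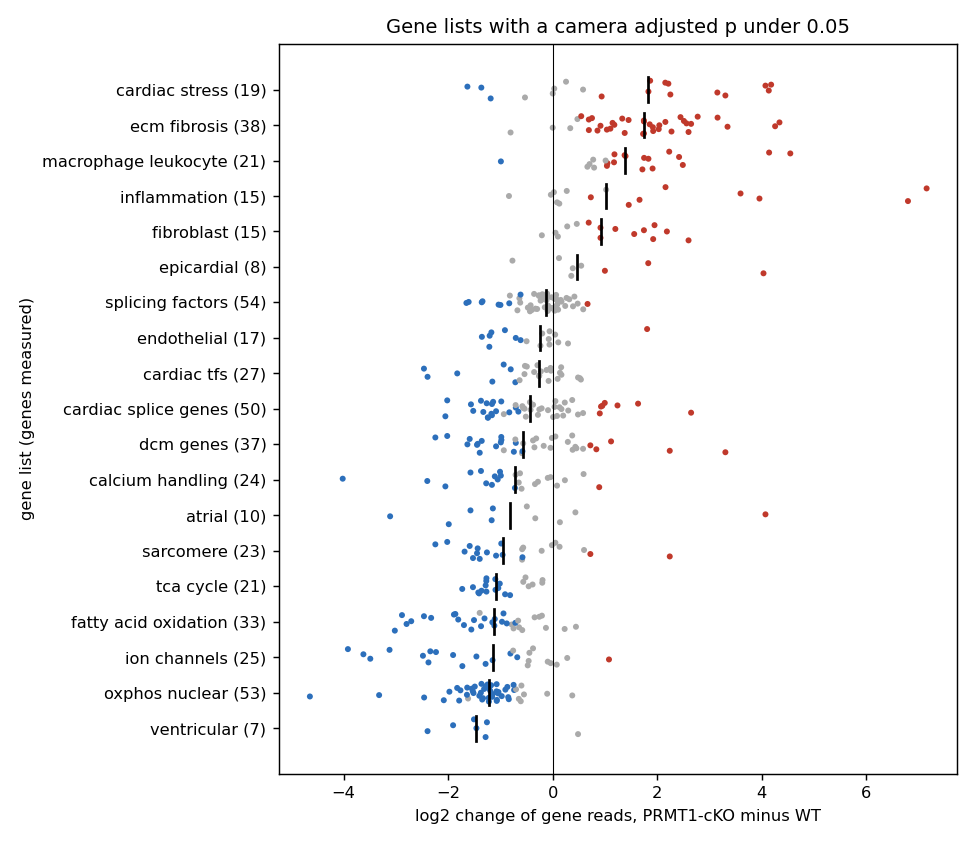
Each point is the log2 change of 1 gene (PRMT1-cKO minus WT, gene reads) in the lists with a camera adjusted p under 0.05, with the number of genes measured in brackets. Red and blue points rose and fell with an edgeR adjusted p under 0.05, grey points did not pass, and black bars are list medians, which run from -1.46 for ventricular markers to 1.83 for cardiac stress genes.

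Many stress and fetal genes of the heart rose. Of 19 measured members 11 rose, 3 fell and 5 did not pass (12 and 4 when adjusted over the list alone). Nppa went from 129 ± 34.9 to 2163 ± 222 CPM of gene reads (SD, n = 2 each), a log2 change of 4.07 ± 0.37 (edgeR adjusted p = 1.86e-07). Nppb rose by a log2 change of 4.18 ± 0.28, the endothelin gene Edn1 by 4.14 ± 0.35 and Ankrd1, a titin-binding stress protein of the sarcomere, by 3.31 ± 0.33. The members that fell were Acta1, the skeletal actin gene, at -1.19 ± 0.31, Mybpc2 at -1.37 ± 0.29 and Myh7, the slow myosin heavy chain, at -1.63 ± 0.23 in gene reads. Exon reads of Myh7, from its spliced RNA, rose by a log2 change of 5.68 ± 0.40 (edgeR adjusted p = 2.17e-08). The Acta1 call was lost without WT replicate 2 (edgeR adjusted p = 0.241) and without PRMT1-cKO replicate 2 (0.0876), and that of Mybpc2 without WT replicate 2 (0.0549). Against other genes the list passed with the preset correlation (camera adjusted p = 1.12e-04) and not with an estimated correlation (camera adjusted p = 0.465). Nor did it pass with fry, which tests a list against no change (fry adjusted p = 0.0558).

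Many genes of contraction and of the action potential fell. In the sarcomere list 13 of 23 fell and 2 rose (15 and 3 when adjusted over the list alone). Tnni3, cardiac troponin I, had a log2 change of -2.25 ± 0.24, the giant sarcomere protein gene Ttn -2.02 ± 0.32 and the light chain gene Myl3 -1.69 ± 0.24. Des, the muscle intermediate filament gene, rose 4.73-fold from 76.7 ± 12.1 to 363 ± 67.9 CPM (SD, n = 2 each, edgeR adjusted p = 7.49e-06), and Mybpc3 rose by a log2 change of 0.72 ± 0.25, a call lost without WT replicate 1 (edgeR adjusted p = 0.288), WT replicate 2 (0.335) or PRMT1-cKO replicate 1 (0.197). In the calcium list 12 of 24 fell and 1 rose (14 and 2 when adjusted over the list alone). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, was 16.2-fold lower, Casq1 5.28-fold lower and Atp2a2 4.15-fold lower, while the sodium pump subunit gene Atp1b1 rose by 0.89 ± 0.21 on the log2 scale (edgeR adjusted p = 0.149 without WT replicate 2). In the ion channel list 15 of 25 fell (15 when adjusted over the list alone). The potassium channel genes Kcnj3 and Kcnd2 had log2 changes of -3.62 ± 0.32 and -3.49 ± 0.29, and the sodium channel genes Scn4a and Scn4b of -3.12 ± 0.31 and -3.92 ± 0.72. Kcnj3 had 1 exon read in each library, so its fall rests on reads outside exons. Camera adjusted p was 1.12e-04 for the sarcomere, 3.07e-05 for calcium and 4.76e-08 for ion channels, and adjusted p = 0.392, 0.419 and 0.392 with an estimated correlation.

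Many genes of mitochondrial energy metabolism fell. Of 53 nuclear-encoded respiratory chain and ATP synthase genes, 45 fell and 0 rose (49 and 0 when adjusted over the list alone), with a median log2 change of -1.21. The muscle isoform genes of cytochrome c oxidase had log2 changes of -4.65 ± 0.29 for Cox7a1, -3.32 ± 0.23 for Cox8b and -2.46 ± 0.21 for Cox6a2. In fatty acid oxidation 21 of 33 genes fell and 0 rose (25 and 1 when adjusted over the list alone). The thiolase gene Acaa2 fell 8.13-fold from 149 ± 17.1 to 18.3 ± 0.0556 CPM (SD, n = 2 each, edgeR adjusted p = 5.04e-08). Ppargc1a, a coactivator of mitochondrial genes, fell 7.39-fold, Eci1 6.95-fold and Etfb 6.54-fold. In the citric acid cycle 15 of 21 genes fell and 0 rose (18 and 0 when adjusted over the list alone), Idh2 by a log2 change of -1.73 ± 0.22 and Idh3b by -1.53 ± 0.24. Camera adjusted p was 7.75e-21 for the respiratory chain, 8.02e-13 for fatty acid oxidation and 4.74e-09 for the citric acid cycle, and adjusted p = 0.392 for each with an estimated correlation. Glycolysis genes split, with 6 higher and 7 lower of 22 (8 and 7 when adjusted over the list alone, camera adjusted p = 0.836; the median log2 change was 0.13 and the mean -0.15). The glucose transporter gene Slc2a1 rose 5.61-fold and Slc2a4, the insulin-responsive transporter, fell 5.38-fold. The 13 protein genes of the mitochondrial genome had 0 reads in every library and were not tested. The mt-Rnr2 share of reads was lower in the same hearts, as given above. Its log2 change of -0.84 ± 0.93 did not pass the edgeR test, though it passed with DESeq2, as given below. Ribosomal RNA had been removed before sequencing, so this share cannot be read as mitochondrial RNA content.

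**Figure D2:**
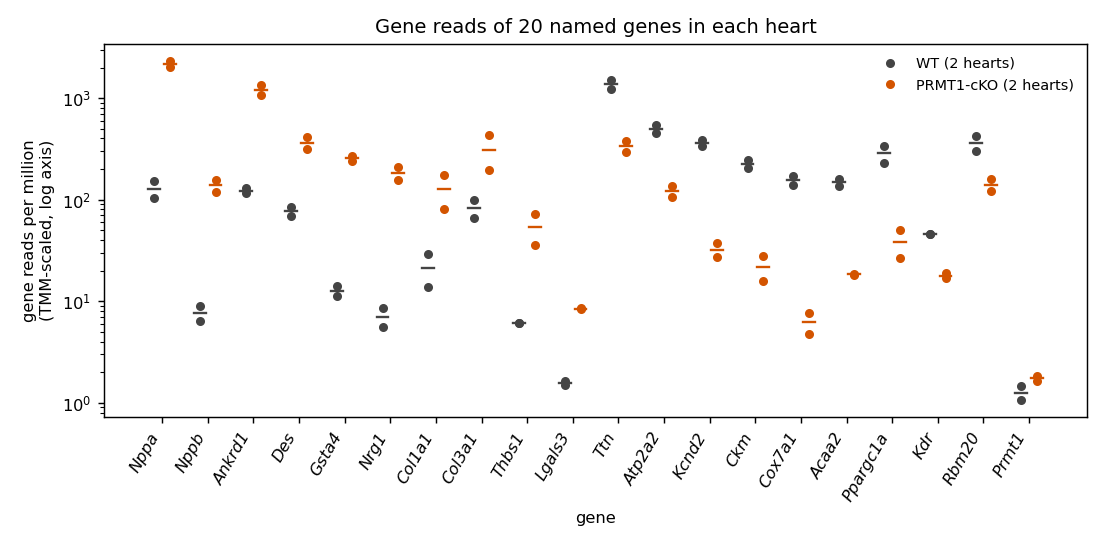
Points show TMM-scaled CPM of gene reads (log axis) of 20 named genes in each of the 2 WT and 2 PRMT1-cKO hearts, with bars at the group means. Nppa stood at 129 ± 34.9 in WT and 2163 ± 222 in PRMT1-cKO (SD, n = 2 each), Cox7a1 at 155 ± 20.6 and 6.21 ± 2.04, and Prmt1 at 1.26 ± 0.289 and 1.73 ± 0.156.

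Genes of the extracellular matrix rose almost throughout. Of 38 measured matrix and fibrosis genes 34 rose and 0 fell (34 and 1 when adjusted over the list alone), with a median log2 change of 1.75. Comp, a cartilage and tendon matrix protein, rose by 3.35 ± 0.26, the thrombospondin gene Thbs1 by 3.16 ± 0.28, and the lysyl oxidase relative Loxl2 by 4.34 ± 0.57 from a low level (3 and 1 gene reads in WT and 56 and 38 in PRMT1-cKO). Cthrc1 rose from 0 and 1 gene reads in WT to 16 and 10 in PRMT1-cKO. Fibroblast markers rose in 10 of 15 cases and fell in 0 (10 and 0 when adjusted over the list alone). Col1a1 rose by 2.60 ± 0.35, Col3a1 by 1.92 ± 0.33 and the fibroblast transcription factor gene Tcf21 by 1.95 ± 0.44, and Col1a1, Col3a1, Dcn and Lum are in the matrix list too. Like Col1a1, Col3a1 differed between hearts of a group, with 82.1 ± 23.1 CPM in WT and 311 ± 166 CPM in PRMT1-cKO (SD, n = 2 each). Camera adjusted p was 1.69e-15 for matrix and 1.92e-04 for fibroblast genes, and adjusted p = 0.419 and 0.430 with an estimated correlation.

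Many leukocyte markers were higher and several endothelial markers lower. Of 21 macrophage and leukocyte markers 15 rose and Fcgr3 fell (16 and 1 when adjusted over the list alone). Lgals3, which encodes galectin-3, rose by 2.42 ± 0.24, the complement gene C1qb by 1.91 ± 0.30, and S100a8, abundant in neutrophils, from 4 and 1 gene reads to 80 and 54. Fcgr3 did not pass without WT replicate 1 (edgeR adjusted p = 0.0886), WT replicate 2 (0.398) or PRMT1-cKO replicate 2 (0.0843). Inflammatory genes rose in 8 of 15 cases and fell in 0 (8 and 0 when adjusted over the list alone). Saa3 and Cxcl2 had 0 reads in both WT hearts, and against a floor of 3 reads per library they were at least 5.56-fold and at least 4.31-fold higher; Saa3 has close paralogs, so its reads are uncertain. Epicardial markers rose in 3 of 8 cases and fell in 0 (3 and 0 when adjusted over the list alone), Krt18 by 4.04 ± 0.39. The list call was lost without PRMT1-cKO replicate 1 (camera adjusted p = 0.0662). Endothelial markers fell in 7 of 17 cases (8 lower and 1 higher when adjusted over the list alone), Kdr, the VEGF receptor, at -1.36 ± 0.20 and the water channel Aqp1 at -1.21 ± 0.21, while Vwf, von Willebrand factor, rose by 1.81 ± 0.20. Camera adjusted p was 2.44e-08 for leukocyte, 1.92e-04 for inflammatory, 0.0226 for epicardial and 0.0354 for endothelial genes, and adjusted p = 0.430, 0.392, 0.419 and 0.419 with an estimated correlation. The endothelial call was lost with a replicate block (camera adjusted p = 0.111) and without WT replicate 1 (0.0735), WT replicate 2 (0.154) or PRMT1-cKO replicate 1 (0.0662). In exon reads neither the endothelial nor the epicardial list passed (camera adjusted p = 0.450 and 0.121).

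Many chamber markers of cardiomyocytes were lower. Of 7 ventricular markers 6 fell and 0 rose (6 and 0 when adjusted over the list alone), with the transcription factor gene Irx4 at -2.40 ± 0.49 on the log2 scale. Of 10 atrial markers 5 fell and Nppa rose (6 and 1 when adjusted over the list alone), with Myl7, the atrial light chain gene, at -3.11 ± 0.23 and Bmp10 at -1.99 ± 0.37. Camera adjusted p was 6.01e-04 and 0.0318, and adjusted p = 0.392 and 0.419 with an estimated correlation. The atrial call was lost with a replicate block (camera adjusted p = 0.0663) and without WT replicate 1 (0.0535), WT replicate 2 (0.0647) or PRMT1-cKO replicate 1 (0.0953), and with the stricter read filter (0.113). In exon reads 2 atrial markers rose and 3 fell of 9 (2 and 3 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.700). Mural markers (2 higher, 1 lower of 13, 2 and 1 when adjusted over the list alone), nerve and Schwann cell markers (1 and 2 of 5, 1 and 2 when adjusted over the list alone) and adipocyte genes (1 and 1 of 9, 1 and 1 when adjusted over the list alone) did not pass as lists (camera adjusted p = 0.836, 0.187 and 0.991). Des is counted in both the mural and the sarcomere list. Ucp1, the thermogenic uncoupling protein gene of brown fat, fell 9.19-fold, and Cfd, adipsin, rose 2.44-fold, a call lost without WT replicate 1 (edgeR adjusted p = 0.0735) and without PRMT1-cKO replicate 1 (0.677). Lists with fewer than 5 measured members were not tested as lists. Among them, Ckm, muscle creatine kinase, fell 10.3-fold, and the red cell enzyme gene Alas2 went from 14 and 0 gene reads in WT to 39 and 55 in PRMT1-cKO. The male-specific genes Uty and Ddx3y had reads in all 4 hearts, and neither passed the test, though Uty did without PRMT1-cKO replicate 2 (edgeR adjusted p = 0.0160). The histone gene Hist1h2bc had a log2 change of -0.05 ± 0.22 that did not pass.

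Several regulators of splicing and of transcription fell in gene reads. Of 54 splicing regulators 8 fell and 1 rose (8 and 0 when adjusted over the list alone), among them Rbfox1 at -1.65 ± 0.27, Rbm24 at -1.61 ± 0.20, Rbm20, a regulator of titin splicing, at -1.36 ± 0.28 and Rbm38 at -1.34 ± 0.27. Exon reads of Rbm24 did not pass, with a log2 change of -0.17 ± 0.23 (edgeR adjusted p = 0.612). Those of Rbm20 fell by a log2 change of -1.43 ± 0.35 (edgeR adjusted p = 0.00451). Rbfox1 had 14 and 5 exon reads in WT and 0 and 0 in PRMT1-cKO. Rbm38 had 1 and 0 in WT and 0 and 0 in PRMT1-cKO. Both had too few to test, so their calls rest on reads outside exons. The Rbm20 call was lost without WT replicate 1 (edgeR adjusted p = 0.0738). Heart genes with known alternative splicing fell in 18 and rose in 7 of 50 cases (22 and 9 when adjusted over the list alone), with Fn1 at 2.65 ± 0.23 and Sorbs2 at 1.63 ± 0.32. Genes of inherited dilated cardiomyopathy fell in 15 and rose in 5 of 37 cases (17 and 6 when adjusted over the list alone). Heart transcription factor genes fell in 7 and rose in 0 of 27 cases (9 and 0 when adjusted over the list alone), with Ppara, a regulator of fatty acid oxidation, at -2.46 ± 0.24 and Myocd at -1.83 ± 0.28. Myocd had 3 and 6 exon reads in WT and 2 and 9 in PRMT1-cKO, too few to test. Camera adjusted p was 0.0395, 0.0108, 0.0150 and 0.0127 for these 4 lists in this order, and adjusted p = 0.701, 0.647, 0.392 and 0.465 with an estimated correlation. All 4 calls were lost without PRMT1-cKO replicate 1 (camera adjusted p = 0.242, 0.0953, 0.0610 and 0.0560), and those of splicing regulators, splice genes and cardiomyopathy genes also without WT replicate 1 (0.243, 0.0535 and 0.0535). That of the splicing regulators was also lost with a replicate block (camera adjusted p = 0.0785) and with the stricter read filter (0.0644). In exon reads none of the 4 passed (camera adjusted p = 0.283, 0.676, 0.700 and 0.700).

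The remaining lists did not pass as lists in gene reads with all 4 hearts. Circadian clock genes fell in 6 of 15 cases and rose in 1 (7 and 2 when adjusted over the list alone, camera adjusted p = 0.0674), with the clock activator Arntl at 1.77 ± 0.24 and the clock output gene Dbp at -1.59 ± 0.30. That list passed without a read filter (camera adjusted p = 0.0165) and in intron reads (0.0406). Reported substrates and partners of PRMT1 rose in 2 and fell in 1 of 25 cases (1 and 1 when adjusted over the list alone, camera adjusted p = 0.968). The p53 and DNA damage list had 4 higher and 2 lower of 14 (4 and 2 when adjusted over the list alone, camera adjusted p = 0.384), with Plk2 at 2.49 ± 0.24. Cell cycle genes had 3 higher and 2 lower of 19 (5 and 3 when adjusted over the list alone, camera adjusted p = 0.144), with Ccnd1, cyclin D1, at -1.59 ± 0.29. That list passed without WT replicate 2 (camera adjusted p = 0.0474), without PRMT1-cKO replicate 2 (0.00284) and without a read filter (0.0374). Immediate early genes had 1 higher and 2 lower of 13 (1 and 2 when adjusted over the list alone, camera adjusted p = 0.148, 0.0208 without PRMT1-cKO replicate 1 and 0.0176 in intron reads). Stress response genes of the unfolded protein and amino acid pathways had 1 higher and 2 lower of 24 (1 and 2 when adjusted over the list alone), with the amino acid transporter gene Slc7a5 at 2.67 ± 0.44. Proteasome and autophagy genes had 5 and 4 of 29 (6 and 4 when adjusted over the list alone), with the autophagy receptor gene Sqstm1 at 1.47 ± 0.20 and the muscle ubiquitin ligase gene Trim63 at -1.43 ± 0.20. Cell death genes had 2 and 1 of 18 (1 and 1 when adjusted over the list alone), and interferon-stimulated genes 2 and 2 of 18 (2 and 2 when adjusted over the list alone). Camera adjusted p for these last lists was 0.968, 0.836, 0.647 and 0.904, and 0.836 for the PRMT family.

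Among genes with at least 5 CPM and no overlap between the groups, which chance gives to 1 gene in 3, the largest rise in gene reads was that of Nmrk2 (chromosome 10, 81198170 to 81202037 on GRCm38), a muscle kinase of nicotinamide riboside, with 4 and 14 gene reads in WT and 715 and 251 in PRMT1-cKO and a log2 change of 5.61 ± 0.54 (edgeR adjusted p = 3.75e-07). Nmrk2 stood at 0.498 ± 0.454 CPM in WT and 22.8 ± 17.4 CPM in PRMT1-cKO (SD, n = 2 each), so its size and rank are uncertain. Star, which carries cholesterol into mitochondria for steroid synthesis, followed at 5.26 ± 0.32, then the matrix metalloproteinase gene Mmp3 at 5.22 ± 0.35, the acute-phase gene Serpina3n at 5.20 ± 0.31, Gsta1 at 5.19 ± 0.37, the matricellular gene Wisp2 at 4.92 ± 0.27, the growth factor gene Nrg1 at 4.69 ± 0.30 and Gsta4 at 4.33 ± 0.28. WT gene reads were few for Star (9 and 11), Mmp3 (3 and 8), Serpina3n (10 and 14) and Gsta1 (7 and 4), so their order is uncertain too. Gsta1 and Gsta2 are close paralogs, so the split of reads between them is uncertain, and the same holds for Ces1d and its paralogs. The largest fall was that of the kinase gene Mylk4 (chromosome 13, 32700827 to 32783954 on GRCm38), with 4879 and 2812 gene reads in WT and 66 and 73 in PRMT1-cKO and a log2 change of -5.92 ± 0.30 (edgeR adjusted p = 6.55e-10). Plscr5 followed at -5.80 ± 0.34, the carboxylesterase gene Ces1d at -4.65 ± 0.26, Cox7a1 at -4.65 ± 0.29, the mitochondrial glutathione transferase gene Gstk1 at -4.29 ± 0.26, Itgb6 at -4.12 ± 0.32, the triglyceride synthesis gene Dgat2 at -4.03 ± 0.26 and Hrc at -4.02 ± 0.24.

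Exon reads, which cross exon junctions and so come from spliced RNA, changed in the same direction as gene reads for most genes that passed in both. Of 4756 genes tested, 1723 changed in exon reads, 835 higher and 888 lower (edgeR adjusted p under 0.05). This second comparison was chosen after the columns of the table had been seen. Of 4743 genes tested in both kinds of reads, 555 were higher in both, 553 lower in both and 6 changed in opposite directions. Gene reads include the exon reads, so part of this overlap is built in. Of the same 4743 genes, 292 passed in gene reads only and 603 in exon reads only. Nppa rose 16.0-fold and Ankrd1 by a log2 change of 3.21 ± 0.10 (SE, n = 2 per group), while Acaa2 changed by -3.34 ± 0.14, Ckm by -3.49 ± 0.14 and Cox7a1 by -4.80 ± 0.15. All 43 measured respiratory chain genes and all 18 measured citric acid cycle genes fell, and in fatty acid oxidation 23 of 25 did, with the same counts when adjusted over the list alone. Matrix genes rose in 25 of 30 cases (26 when adjusted over the list alone). Camera adjusted p in exon reads was 1.25e-16, 2.77e-08, 6.80e-11 and 1.06e-10 for these lists, and adjusted p = 0.414 for each with an estimated correlation. Of 29 lists tested, 12 changed, each of them also changed in gene reads, and with camera at an estimated correlation 0 did (1 had an unadjusted p under 0.05, and 12 passed with fry, 10 of them among the 12 of camera; the fibroblast and leukocyte lists did not pass with fry).

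Several genes had exon reads in 1 group only, for which a fold is a bound against a floor of 3 reads per library. Arg1, which encodes arginase of the urea cycle and of macrophages, had 0 and 0 exon reads in WT and 149 and 114 in PRMT1-cKO, at least 36.4-fold higher. Psca was at least 32.6-fold, the epithelial and injury gene Sprr1a at least 26.1-fold, Gsta2 at least 11.9-fold, the macrophage chitinase-like gene Chil3 at least 11.9-fold, Cfap52 at least 9.98-fold and Tnni1, the slow skeletal troponin I of the fetal heart, at least 5.75-fold higher; Gsta2 and Chil3 have close paralogs, so their reads are uncertain. Star had 1 and 0 exon reads in WT and 416 and 287 in PRMT1-cKO. In the other direction Rpl3l, a muscle paralog of a ribosomal protein, was at least 8.93-fold, Smco1 at least 8.52-fold, Scn4b at least 7.56-fold and Cth, an enzyme of cysteine synthesis, at least 4.78-fold lower. The muscle fructose bisphosphatase gene Fbp2 had 74 and 66 exon reads in WT and 0 and 1 in PRMT1-cKO, Ky had 60 and 45 exon reads in WT and 3 and 0 in PRMT1-cKO, and Hamp, hepcidin, had 28 and 11 exon reads in WT and 0 and 1 in PRMT1-cKO.

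**Figure D3:**
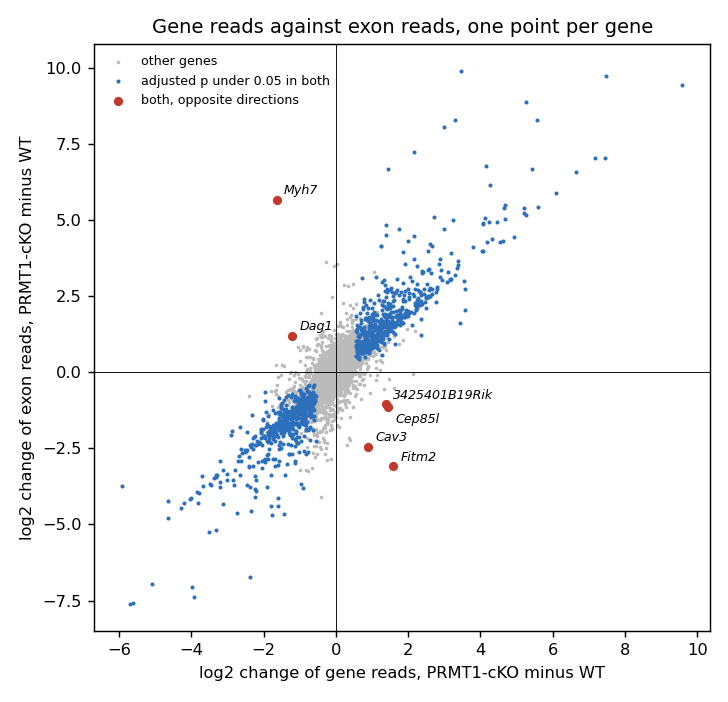
Each point is 1 of 4743 genes, placed by its log2 change (PRMT1-cKO minus WT) in gene reads (horizontal axis) and in exon reads (vertical axis). Blue points passed the edgeR test in both, and the 6 red points changed in opposite directions, Myh7 by -1.63 in gene reads and 5.68 in exon reads; fitted values of genes with 0 reads in a group depend on the prior count.

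Exon reads were also set against intron reads within each gene. The comparison shows where the exon reads counted and the reads outside exons changed by different factors. In genes with several transcripts exon reads may follow single transcripts, as set out at the end. Tnnt2 has 13 annotated transcripts, Lmo7 16, Rtn4 10 and Vldlr 8, so a shift between transcripts could give such a difference there. Myh7 (chromosome 14, 54970688 to 54994634 on GRCm38) had 1 and 4 exon reads in WT and 185 and 136 in PRMT1-cKO, while its intron reads fell, so the exon change exceeded the intron change by 7.91 on the log2 scale (edgeR diffSpliceDGE with Simes adjusted p = 2.78e-57). This difference was 7.09 without WT replicate 1 and 9.29 without WT replicate 2. The Myh7 region also holds the noncoding gene Mhrt and the microRNA gene Mir208b, whose reads cannot be told apart from Myh7 intron reads where they overlap. Acaa2 went the other way in this joint fit of exon and intron reads, whose values differ slightly from those of the separate fits, with an exon change of -3.29 and an intron change of -0.30 (Simes adjusted p = 4.47e-16 from edgeR). The difference between exon and intron change was -2.93 for the lipoprotein receptor gene Vldlr, -3.48 for Cmss1 and -5.70 for the lipid droplet gene Fitm2, and for 3425401B19Rik the exon change was -0.98 and the intron change 2.01. Of 4292 genes tested, 158 changed in this balance, 80 with exon reads up relative to intron reads and 78 with exon reads down. Of 43 tested heart genes known for alternative splicing 5 changed, with exon reads up relative to intron reads in Tnnt2, cardiac troponin T, by 1.52, in Nexn by 1.04, in Lmo7 by 1.61 and in Rtn4 by 3.03, and the reverse in Asb2, with a difference of -2.17. Of these 5 calls, those of Tnnt2, Nexn, Rtn4 and Lmo7 were lost without WT replicate 1 (edgeR Simes adjusted p = 0.303, 0.992, 0.694 and 0.212), those of Nexn, Asb2 and Rtn4 without WT replicate 2 (for Asb2 0.0638, for Rtn4 0.526, and for Nexn with a difference of 0.98), and those of Nexn and Rtn4 without PRMT1-cKO replicate 1 (0.381 and 0.219). Sizes moved as well: the difference was -5.02 for Fitm2 without WT replicate 2, -3.00 and -1.44 for Asb2 without PRMT1-cKO replicate 1 or 2, and 2.38 and 3.79 for Rtn4 without the same libraries. With a replicate block the calls of Nexn (0.290) and Rtn4 (0.0842) were lost. The count and its split depend on single libraries: 25 genes changed without WT replicate 1 (5 up and 20 down), 30 without WT replicate 2 (20 and 10), 185 without PRMT1-cKO replicate 1 (47 and 138) and 302 without PRMT1-cKO replicate 2 (255 and 47), against 69 with a replicate block (33 and 36). This test compares spliced with other reads of a gene, and the use of single exons or transcripts was not analysed here.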

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

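The replicate numbers 1 and 2 do not come from a stated pairing of the hearts. Deviations of same-numbered libraries from their group means had a correlation of -0.124 across genes in gene reads, and with the replicate block the genes changed between PRMT1-cKO and WT numbered 2806, the lists 16, the genes changed in exon reads 1583 and the Prmt1 log2 change was 0.46. With the numbers crossed, chosen after seeing the data, 4329 genes changed, all 3154 of the main count among them, and 1804 in exon reads. The genes changed in the balance of exon and intron reads fell from 158 to 69 with the block, were 335 with the F test in place of Simes, 109 with 5 times the read minimum, and ran from 25 to 302 when each library was left out. Leaving out each library gave 1869 to 3274 genes changed in gene reads, 1203 to 1735 in exon reads, 13 to 20 lists, and 127 to 141 of the 147 named genes that had passed. A left-out library leaves 1 heart in a group, which is taken to vary like the pair in the other group. The DESeq2 test called 2201 genes in gene reads and 1096 in exon reads (1723 by edgeR), without a list test. RLE size factors, no filter and the stricter filter gave 3153, 3299 and 2609 genes. Prmt1 had too few reads for the stricter filter, kept its direction elsewhere and passed nowhere.

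Of the settings chosen after seeing the data, exon reads called 1723 genes in place of 3154, tested on fewer genes, 12 lists in place of 19, and 97 of the 113 passing named genes tested there. Intron reads called 2886 and the fit without mitochondrial and exonless genes 3147. Among named genes that passed in gene reads or in the alternative, changes of sign in exon reads were those of Myh7 (5.68), Vldlr (-2.38), Fitm2 (-3.09), 3425401B19Rik (-1.06), Tnnt2 (0.37), Fcgr3 (0.72) and Nexn (0.0510), and in intron reads that of Top2a (-0.16); the cause was not tested. Prmt7 (0.51), Prmt5 (-0.51), Hist1h2bc (0.22) and Ddx3y (-0.00679) also changed sign in intron reads and passed in neither. Camera with an estimated correlation called 0 lists in gene reads and 0 in exon reads, and fry called 6 and 12, of which 6 and 10 were called by camera too. Fry and the estimated correlation rest on 2 residual degrees of freedom.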

Other observations

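The tests of overlap and of read numbers for the balance of exon and intron reads were written before their results were seen. Those of cell shares, of dilution, of transcript number (both) and the list of NRF2 targets as tested were set after values they rest on had been seen. In gene reads Gsta4 rose by a log2 change of 4.33 ± 0.28 (SE, n = 2 per group), Gstm1 by 3.38 ± 0.23 and Gsta1 by 5.19 ± 0.37, and the heme oxygenase gene Hmox1 rose by 4.09 ± 0.29 and the thioredoxin reductase gene Txnrd1 by 2.59 ± 0.24, while Gstk1 changed by -4.29 ± 0.26 and Mgst3 by -1.78 ± 0.20. Gstm1, Mgst3, Hmox1 and Txnrd1, and the single genes named below, were chosen after their values were seen. A hypothesis is that targets of NRF2, a transcription factor of the oxidative stress response, rose as a group. It was tested on 27 other genes commonly listed as targets. A first run also held Hmox1 and Txnrd1, which were then left out because their values had already been seen (29 genes, 16 of 28 measured higher, median log2 change 1.04, camera p = 5.02e-10, p = 0.0197 with an estimated correlation). Of 26 measured, 14 rose and 0 fell (edgeR adjusted p under 0.05; 16 and 0 when adjusted over the list alone), with a median log2 change of 0.93. Camera gave p = 1.70e-08 with the preset and p = 0.0242 with an estimated correlation. The p-values for this list are not adjusted over lists, unlike those of the fixed lists above. Unadjusted, camera with an estimated correlation gave p = 0.0216 for fatty acid oxidation, 0.0440 for the sarcomere and 0.0494 for the respiratory chain. None of these passed after adjustment (camera adjusted p = 0.392 for each). Without Mgst1, a membrane transferase that the NRF2 list holds, the median was 0.82 (camera p = 6.05e-08, p = 0.0264 with an estimated correlation). Among the members, Gclc, which limits glutathione synthesis, rose by 2.45 ± 0.22, Srxn1 by 2.91 ± 0.34 and Taldo1 by 2.04 ± 0.23. Other factors may raise the same genes, and the cells in which they rose were not resolved here.

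Of 22 mitochondrial RNA genes tested, 14 fell in gene reads and 0 rose, all of those that fell being transfer RNA genes, such as, chosen after their values were seen, mt-Tl1 at -1.74 ± 0.35 and mt-Ti at -1.61 ± 0.28 (SE, n = 2 per group). mt-Rnr2 had a log2 change of -0.84 ± 0.93 and mt-Rnr1 of 0.24 ± 0.52, and neither passed the edgeR test, while mt-Rnr2 passed with DESeq2 (DESeq2 adjusted p = 5.70e-04).

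Many heart muscle genes fell while matrix and leukocyte genes rose. If a lower share of heart muscle cells were the whole cause, markers of every other cell type would rise alike, but the mean log2 change was 1.09 over 15 fibroblast markers and -0.36 over 17 endothelial markers, a difference of 1.45 (permutation p = 6.00e-05 over genes, 100000 resamples). This p takes genes as independent, which they are not, and does not measure the spread between hearts. With an estimated correlation neither list passed against other genes (camera adjusted p = 0.430 and 0.419). Dilution by RNA of other cells would lower muscle genes by 1 shared factor, but the log2 changes of 72 sarcomere, calcium and ion channel genes had an SD of 1.16, which is 4.71 times the median standard error of a gene, and 4 of them rose. Either process may still add to the changes, and more fibroblasts and leukocytes, fewer endothelial cells and altered transcription within cardiomyocytes stay open.

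Exon and intron reads of 158 genes changed by different factors. Reads of an overlapping annotated gene may account for some of them, as at Myh7, but 55.7% of the 158 and 51.4% of the other 4134 tested genes overlap another gene (odds ratio 1.19, Fisher's exact p = 0.293), which does not settle it. Median exon reads over the 4 libraries were 323 in the changed and 154 in the other genes, a ratio of 2.10, but a test calls more genes at higher read numbers whatever the cause, so this leaves few reads open. With 5 times the read minimum 109 genes changed, 95 of the 158 among them. Altered splicing or retention of introns in PRMT1-cKO hearts stays open, as does a shift between transcripts where exon reads follow single transcripts. None of these was tested.

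Genes with many annotated transcripts had few exon reads, which bears on Prmt1, with 8 transcripts and 0 exon reads. Among genes with at least 4 exons and at least 400 intron reads over the 4 libraries, median exon reads were 349 for the 1058 genes with 1 transcript and 8 for the 993 with 9 or more. In the 25% of these genes with the most intron reads, the median was 15.5 with 5 or more transcripts. With 1 transcript it was 602, which gives a ratio of 0.0257. Few intron reads are therefore not the cause. Intron reads do not measure spliced RNA, so low abundance of spliced RNA stays open. A candidate explanation is that reads fitting several transcripts were not counted: among genes with 2 to 4 transcripts exon reads rose with the share of junctions found in 1 transcript only (Spearman rho 0.311 across genes, which are not independent). For such genes exon reads may then follow single transcripts more than the gene, and no biological explanation was tested.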
